A study of Mus musculus with 8 samples.

How the data were processed

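Total RNA of 8 Ba/F3 samples was measured on Agilent 4x44K mouse arrays, 1 array per sample and 1 dye (Cy3), in 4 groups of 2 arrays. Per the file headers, the deposited intensity values had been background-subtracted and corrected on each array by Agilent Feature Extraction (version 9.5.1.1 for set 1 and 10.7.3.1 for set 2), with no scaling between arrays. The foreground and local background intensity columns were used only for one alternative. For the main analysis log2 was taken here of the deposited processed intensity, and each array's 75th percentile (937 to 1109 in set 1, 367 to 600.0 in set 2) was subtracted. The authors' normalized tables hold deposited values, where each column lay within 0.01 log2 of a single array's median-scaled values for 99.7 to 100% of probes. They served as an alternative.

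Control spots were left out, and spots marked as outliers (93 to 203 per array) were set to missing. Of 45018 spots, 43379 were of 41174 probes, and spots of a probe were averaged. A probe was kept if well above background on both arrays of at least 1 group, which left 21126 probes. The kept probe with the highest mean signal stood for its gene, giving 13740 genes. Genes were named by the accession (27698 probes), symbol (5644) or synonym (678) in the gene reference given, or by the file's name alone (1284), and 5870 probes had no gene name. Probe coordinates are those of mm9 in the set 2 files, and no genome annotation was used.

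All 8 arrays were fitted together with limma 3.58.1 (R 4.3.3 and data.table, version 1.17.8), with 4 group means and the array set as block, and eBayes with an intensity trend. The fit left 3 residual degrees of freedom. The slide in the file headers gave the pairing. Arrays of a set shared their deviations from the group means, with correlations of 0.731 to 0.879. Arrays of the same slide correlated at 0.957 to 0.99 and those of the same group at 0.922 to 0.944, and the first component (64% of variance) separated the slides. The 7 comparisons were ITD without and with Cxcl12, Cxcl12 in each kind of cell, the averages of both and the interaction. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" are used of these alone.

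The 25 gene lists, the comparisons with their tests and the alternatives named below were fixed before the data were examined. The closing section says which further tests were chosen later. The 25 lists were STAT5 targets, MAPK feedback genes, immediate-early genes, FOXO targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, BCL2 and IAP families, MYC targets and ribosome biogenesis, cholesterol synthesis and uptake, ATF4 and amino acid response, unfolded protein response, heat shock, glycolysis and hypoxia, interferon-stimulated genes, NF-kB targets, CXCR4 signalling and migration, adhesion molecules, haematopoietic transcription factors, and markers of pro-B cells, mast cells and basophils, neutrophils and granules, monocytes and macrophages, T and NK cells and erythroid cells. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists. They were tested again with the correlation estimated from the data. The latter test also has only the 3 residual degrees of freedom of the fit, while the preset test has far more. A higher p with the estimated correlation thus need not come from correlation between genes. An example is neutrophil and granule markers with Cxcl12 in wild type FLT3 cells. The camera adjusted p went from 0.0368 to 0.49 there, at an estimated correlation of -0.108. Overlap was tested with Fisher's exact test.

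Named genes were, per comparison, up to 10 higher and 10 lower genes with the largest differences that passed and had the same direction in both sets. Open places went to genes at least 2-fold different in both sets and well above background on both arrays of the higher group, stated as not past the test. Up to 4 passing members of each list were added, and always Flt3, Cxcr4, Ackr3, Cxcl12, Cdkn1a, Runx1, Rock1 and Birc5. Some genes are not reported here, though the counts hold them. The text names a selection of these, those with a well known function first, and list members that did not pass as examples. In the average ITD effect 304 called genes had several probes, and 21 of them had a probe of the opposite sign, against 0 of 15 in the average Cxcl12 effect.

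The fit was tested on simulated data with 100 changed genes per fold. For the average ITD effect it recovered 86% of 2-fold and 99% of 4-fold changes, and for the average Cxcl12 effect 70% and 100%. It recovered 35% and 92% for ITD without Cxcl12, 34% and 91% for ITD with Cxcl12, 33% and 97% for Cxcl12 in wild type FLT3 cells, 19% and 90% for Cxcl12 in FLT3/ITD cells, and 4% and 64% for the interaction. Between 6 and 16 unchanged genes were called per comparison. A list shifted by 0.7 was called with the preset and with the estimated correlation, and 1 of the other lists was called too with the preset. The simulated genes varied independently, while real lists had estimated correlations as high as 0.57, for MYC targets. The simulation therefore does not show how either list test performs on these data. The number of arrays thus limits the precision, and 2-fold changes are often missed in comparisons of 2 arrays against 2. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples.

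Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, only probes well above background on all 8 arrays, the mean of a gene's probes, no trend in the variance, no array set in the model, the authors' normalized tables, the estimated correlation for lists, and each array left out in turn.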

Results

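mRNA levels were measured in Ba/F3 cells, a mouse pro-B cell line that depends on IL3, carrying either wild type FLT3 or FLT3 with an internal tandem duplication (FLT3/ITD). FLT3 is a receptor tyrosine kinase of blood progenitors, and such duplications switch it on without its ligand. Cells of each kind were kept for 4 h in medium with albumin, with or without 100 ng/ml Cxcl12, the chemokine ligand of the receptor Cxcr4. This gave 4 groups of 2 arrays, 8 arrays in all. Each of 2 slides, called set 1 and set 2 here, held 1 array of each group. The FLT3/ITD arrays of set 1 carry the label N51 and those of set 2 the label N78, so the ITD type and the set cannot be told apart. Between 49.2% and 55.0% of probes were well above background on each array. The comparisons ask which mRNAs differ with FLT3/ITD, which differ with Cxcl12, and whether the difference with Cxcl12 differs between the cells. Differences are log2 values from limma with the standard error (SE), and adjusted p is from limma throughout. Differences in set 1 and set 2 alone rest on 1 array per group and have no test.

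The array's mouse Flt3 probe (chromosome 5, 148159595 to 148159654, mm9) was not well above background on any set 1 array. On the set 2 arrays it was, at -3.86 for wild type FLT3, -4.50 for FLT3/ITD, -4.11 for wild type FLT3 with Cxcl12 and -3.56 for FLT3/ITD with Cxcl12 (log2 intensity relative to the array's 75th percentile). The sources used here do not say whether this probe matches the introduced FLT3, so it does not check the labels. Cxcr4 (chromosome 1, 130485079 to 130485138) was well above background on all 8 arrays. Its average ITD difference was -1.096 (SE 0.29, adjusted p = 0.0564; set 1 -1.70, set 2 -0.49), which did not pass the test, and its average Cxcl12 difference was -0.53 (SE 0.29, adjusted p = 0.439). Another Cxcr4 probe, also well above background on all 8 arrays, was not used in the fit. In set 1 it had 0.94 in FLT3/ITD against 1.87 in wild type FLT3 cells, and -0.61 against 1.85 with Cxcl12. In set 2 it had 0.33 against 0.52, and 0.48 against 0.32 with Cxcl12. Probes of Ackr3, the other Cxcl12 receptor, and of Cxcl12 itself were not well above background on any array.

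FLT3/ITD cells had more mRNA of Pim1, Id1 and Lyz2 and less of Mcpt8 and Clec7a than wild type FLT3 cells. The kinase gene Pim1 rose by 2.48 (SE 0.27, adjusted p = 0.00196; set 1 3.11, set 2 1.84), averaged over cells without and with Cxcl12 (4 arrays against 4). These 4 FLT3/ITD arrays are of 2 ITDs, N51 in set 1 and N78 in set 2, each without and with Cxcl12. The fit pooled the spread between the sets over all groups, so SE and p can understate the spread between the 2 ITDs. Id1, an inhibitor of basic helix-loop-helix transcription factors, rose by 2.41 (SE 0.20, adjusted p = 0.000528; set 1 2.79, set 2 2.03), and Lyz2, a lysozyme of myeloid cells, by 2.57 (SE 0.21, adjusted p = 0.000511; set 1 2.25, set 2 2.88). The mast cell and basophil protease Mcpt8 fell by 4.41 (SE 0.27, adjusted p = 0.000164; set 1 -3.92, set 2 -4.89). Clec7a, the beta-glucan receptor dectin-1, fell by 4.45 (SE 0.28, adjusted p = 0.000164; set 1 -4.02, set 2 -4.88), with 3 of 4 FLT3/ITD arrays above background. In this average ITD effect 847 of 13740 genes passed the test, 492 higher and 355 lower, and 844 of them differed in the same direction in both sets. The test favours genes on which the sets agree, so the 844 do not show that the sets repeat each other. The correlation across genes between the sets was 0.481. Genes are not independent replicates, so it has no p.

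**Figure D1:**
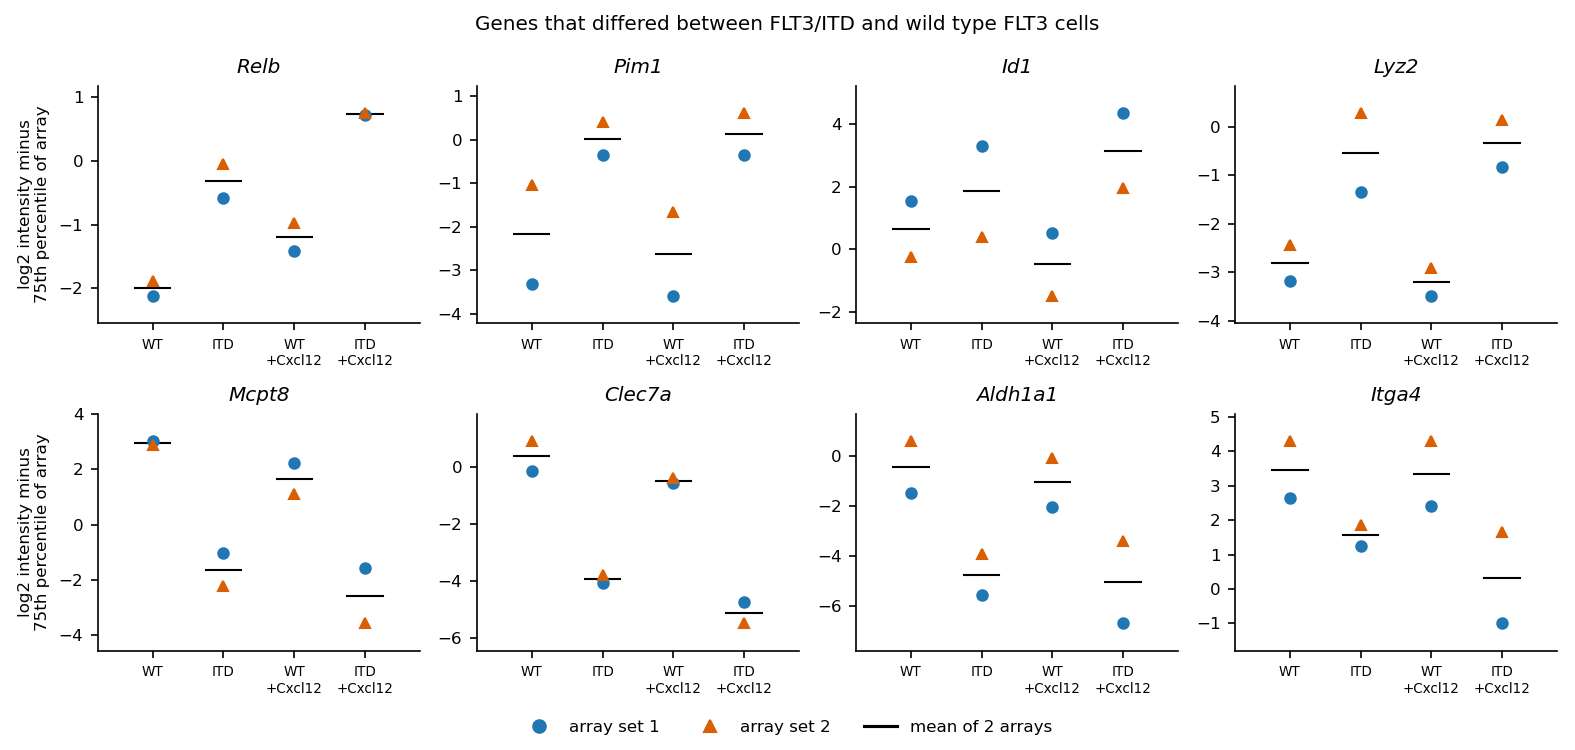
Log2 intensity minus the array's 75th percentile (vertical axes, a scale per panel) of 8 genes in wild type FLT3 (WT) and FLT3/ITD (ITD) cells without and with Cxcl12. Circles are set 1 arrays, triangles set 2 arrays and bars the mean of 2 arrays; Relb, Pim1, Id1 and Lyz2 rose by 1.81, 2.48, 2.41 and 2.57 in the average ITD effect, while Mcpt8, Clec7a, Aldh1a1 and Itga4 differed by -4.41, -4.45, -4.15 and -2.47.

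The highest genes of the average ITD effect included Mrvi1 at 6.42 (SE 0.27, adjusted p = 3.29e-05), with 3 of 4 wild type FLT3 arrays above background. Where only some arrays of a side were above background, the size of the difference is uncertain. Where a probe was not well above background on any array of a side, only a bound is given, taken against the lowest signal above background there. By that rule Kalrn was at least 19.6-fold higher (adjusted p = 0.000461), Slamf1, a receptor of immune cells, at least 9.82-fold (adjusted p = 0.000461), Pglyrp2 at least 9.8-fold (adjusted p = 0.000367) and the zinc transporter gene Slc30a2 at least 4.0-fold (adjusted p = 0.00108). Tcrg, a T cell receptor gamma gene, rose by 4.78 (SE 0.56) and Mylk, a myosin light chain kinase, by 3.91 (SE 0.41; 3 of 4 wild type FLT3 arrays above background). Among the lowest were Dnah11, an axonemal dynein, at -5.06 (SE 0.38; 2 of 4 FLT3/ITD arrays above background), and Ctsg, the granule protease cathepsin G, at -4.83 (SE 0.48). The retinaldehyde dehydrogenase Aldh1a1 fell by 4.15 (SE 0.28; 2 of 4 FLT3/ITD arrays), and its relative Aldh1a7 was at least 7.08-fold lower (adjusted p = 0.000164). Ear6, an eosinophil-associated ribonuclease, fell by 3.49 (SE 0.49; 3 of 4). The probes lie, in mm9, on chromosome 17 from 29630740 to 29630799 for Pim1, chromosome 2 from 152563046 to 152563105 for Id1, and chromosome 14 from 56702300 to 56702674 for Mcpt8.

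Of 12 measured STAT5 targets, which many cytokine receptors induce, 6 rose, 0 fell and 6 did not pass (8 of 12 adjusted over the list alone). Beside Pim1 and Id1 these were Socs1 at 1.97 (SE 0.46), Bcl2l1, which encodes the survival protein BCL-XL, at 1.70 (SE 0.22), Cish at 1.49 (SE 0.35) and the cyclin gene Ccnd2 at 0.61 (SE 0.14). The list's median was 0.65 (set 1 0.91, set 2 0.66, camera adjusted p = 1.32e-06, but adjusted p = 0.453 with an estimated correlation). Id1 is also in the list of haematopoietic transcription factors, where Runx2 and Myb fell by 1.60 (SE 0.28) and 1.05 (SE 0.15). Lmo2 rose there too, and Runx1 had 0.09 (SE 0.17). In the BCL2 and IAP families Bcl2l1 and Bax rose, the latter by 0.81 (SE 0.17), and Bcl2l11, which encodes the death-promoting protein BIM, fell by 0.73 (SE 0.17); 12 of 15 did not pass. The inhibitor of apoptosis Birc5 had 0.01 (SE 0.15).

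All 27 measured MYC targets and ribosome biogenesis genes had positive differences in the average ITD effect. Of them 12 rose, 0 fell and 15 did not pass (26 of 27 adjusted over the list alone). Examples were Srm, spermidine synthase, at 1.68 (SE 0.28), Mybbp1a at 1.41 (SE 0.21) and the nucleolar gene Nolc1 at 1.24 (SE 0.20). The median was 0.77 (set 1 0.55, set 2 0.95, camera adjusted p = 2.7e-14, but adjusted p = 0.453 with an estimated correlation). Of 24 cholesterol synthesis and uptake genes 8 rose, 0 fell and 16 did not pass (13 adjusted over the list alone). Msmo1 and Idi1, enzymes of the pathway, rose by 1.08 (SE 0.17) and 1.06 (SE 0.16). The list's median was 0.56 (set 1 0.38, set 2 0.61, camera adjusted p = 8.22e-08, but adjusted p = 0.453 with an estimated correlation). Of 20 genes of the ATF4 and amino acid response 5 rose and 15 did not pass (10 adjusted over the list alone). Nupr1 rose by 2.89 (SE 0.47; 2 of 4 wild type FLT3 arrays above background), Pycr1 by 1.34 (SE 0.21), Phgdh by 1.04 (SE 0.15), Asns by 1.04 (SE 0.18) and Shmt2 by 0.67 (median 0.45, set 1 0.69, set 2 0.31, camera adjusted p = 5.35e-06, but adjusted p = 0.453 with an estimated correlation). The last 4 encode enzymes that make amino acids.

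Of 14 mast cell and basophil markers 5 fell, 0 rose and 9 did not pass (7 lower and 1 higher adjusted over the list alone). The 5 were the protease genes Mcpt8, Mcpt4 at -3.30 (SE 0.27; 3 of 4 FLT3/ITD arrays above background), Cma1 at -2.90 (SE 0.24) and Cma2 at -2.85 (SE 0.29; 2 of 4), and the receptor gene Cd200r3 at -1.98. Other members lay nearer to 0, among them the histidine decarboxylase gene Hdc at -1.51 (adjusted p = 0.0767; set 1 -2.47, set 2 -0.55), Mitf at 0.50 (adjusted p = 0.124), Cpa3 at -0.78 (adjusted p = 0.256; set 1 0.24, set 2 -1.80), the IgE receptor chain Fcer1a at -0.42 (adjusted p = 0.337, 2 of 4 FLT3/ITD arrays above background) and Gata2 at -0.48 (adjusted p = 0.0819, but 0.04 with normexp background correction). The median was -0.70 (set 1 -0.67, set 2 -0.64, camera adjusted p = 5.08e-07, but adjusted p = 0.453 with an estimated correlation). Of 6 neutrophil and granule markers Ctsg alone passed (2 lower adjusted over the list alone), and the list did not (median -0.05, mean -0.79, camera adjusted p = 0.637). With normexp that list passed, with a median relative to all genes of -0.505 and 0 of 6 members higher (camera adjusted p = 2.66e-06). Of 9 monocyte and macrophage markers 2 rose, the near-identical lysozyme genes Lyz2 and Lyz1. Lyz1 was at least 3.62-fold higher (adjusted p = 0.00504), yet its ITD difference with Cxcl12 was -0.68 with normexp background correction. Its list had a median of -0.15, a mean of 0.18 and a test in the positive direction (camera adjusted p = 0.981). Of 8 T and NK cell markers only Lat, an adaptor of T cell receptor signalling, passed, at 2.08 (SE 0.27; list median 0.07, camera adjusted p = 0.431).

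Of 15 NF-kB targets 4 rose, 1 fell and 10 did not pass (8 higher and 2 lower adjusted over the list alone). Relb, an NF-kB subunit, rose by 1.81 (SE 0.17) and the chemokine gene Ccl5 by 1.63 (SE 0.28). Nfkb1 rose by 0.74, with another of its probes of the opposite sign, and Nfkbiz fell by 0.86 (SE 0.18). Lta was at least 1.31-fold higher, with 3 of 4 FLT3/ITD arrays above background, but had -0.47 with normexp. For the list the median was 0.52 (set 1 0.56, set 2 0.34, camera adjusted p = 0.0171, but adjusted p = 0.453 with an estimated correlation). Of 21 interferon-stimulated genes Usp18 rose by 1.55 (SE 0.33; 2 of 4 wild type FLT3 arrays above background; -0.16 with normexp) and Ifi35 by 0.97 (SE 0.23). Their list's median was 0.19 (set 1 0.15, set 2 0.29, camera adjusted p = 0.0435, but adjusted p = 0.516 with an estimated correlation). Of 14 FOXO targets 3 fell, 0 rose and 11 did not pass (4 lower adjusted over the list alone). These were Sesn3 at -1.29 (SE 0.22), Rbl2 at -0.93 (SE 0.19) and Bcl2l11, in a list with a median of -0.37 (set 1 -0.36, set 2 -0.29, camera adjusted p = 0.0219, but adjusted p = 0.748 with an estimated correlation). The calls of these 3 lists were lost with normexp, with medians relative to all genes of 0.09 for NF-kB targets, -0.08 for interferon-stimulated genes and -0.25 for FOXO targets.

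Of 24 glycolysis and hypoxia genes 2 rose in the average ITD effect, the glucose transporter Slc2a3 by 0.97 (SE 0.16) and Eno1 by 0.68 (SE 0.16), 0 fell and 22 did not pass (2 adjusted over the list alone). Another Slc2a3 probe had the opposite sign. The median was 0.18 (set 1 0.15, set 2 0.22, camera adjusted p = 0.0123, but adjusted p = 0.748 with an estimated correlation), and relative to all genes 0.50 with normexp against 0.19. The list lay at -0.03 without Cxcl12, with 12 of 24 members higher (camera adjusted p = 0.822), and at 0.47 with Cxcl12, with 21 of 24 higher (camera adjusted p = 4.16e-05, but adjusted p = 0.541 with an estimated correlation). The median with Cxcl12 was, relative to all genes, 0.93 with normexp against 0.43. Of 16 adhesion molecules 4 rose and 3 fell, counts that were the same adjusted over the list alone. The integrin gene Itga6 rose by 1.24 (SE 0.27). Itga4, an integrin chain that binds VCAM1, fell by 2.47 (SE 0.28; set 1 -2.40, set 2 -2.53). The list had no direction in common (median 0.10, camera adjusted p = 0.637). Of 25 CXCR4 signalling and migration genes only Rgs2, a regulator of G protein signalling, fell, by 1.07 (SE 0.14); Rock1 had -0.38 (SE 0.15; list median -0.20, camera adjusted p = 0.216).

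Among the other lists, 10 MAPK feedback genes had a median of 0.18 (camera adjusted p = 0.637), with Dusp4 higher at 1.19 (SE 0.26) and Spry2 lower at -0.97 (SE 0.17), another probe of which had the opposite sign. The 16 immediate-early genes had a median of -0.27 (camera adjusted p = 0.394) and none passed. Of 11 heat shock genes Hspd1 and Hspe1 rose by 0.71 and 0.67 (4 higher and 1 lower adjusted over the list alone, median 0.16, camera adjusted p = 0.394). Neither G1/S and DNA replication (29 genes, median 0.01, test in the negative direction) nor G2/M and mitosis (27 genes, median 0.01) passed or held a passing gene, each with a camera adjusted p of 0.981. Of 18 p53 targets (median 0.06, camera adjusted p = 0.915) Bax rose and Fas fell by 0.80, while Cdkn1a had 0.27 (SE 0.16). The BCL2 and IAP families (median -0.004, mean 0.01, camera adjusted p = 0.926) and the haematopoietic transcription factors (17 genes, 3 higher and 5 lower adjusted over the list alone, median -0.12, camera adjusted p = 0.489) did not pass as lists. Of 16 unfolded protein response genes Sdf2l1 rose by 0.74 and Edem1 fell by 0.63 (median 0, camera adjusted p = 0.981). Of 9 pro-B cell markers Ptprc fell by 0.55 (SE 0.13; list median 0.12, camera adjusted p = 0.981), and of 7 erythroid markers Tfrc, the transferrin receptor, rose by 0.92 (SE 0.20; list median 0.02, camera adjusted p = 0.981).

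In cells without Cxcl12 alone (2 arrays against 2), 38 genes were higher and 32 lower in FLT3/ITD cells, 70 in all. The higher ones included Mrvi1 at 6.65 (SE 0.38, adjusted p = 0.000498; 1 of 2 wild type FLT3 arrays above background). Oprk1, an opioid receptor, was at least 7.05-fold higher (adjusted p = 0.0146). The lower ones included Mcpt8 at -4.59 (SE 0.38, adjusted p = 0.00286), Clec7a at -4.28 (SE 0.39), Mcpt4 at -2.75 (SE 0.38) and Cma1 at -2.68 (SE 0.35). Pim1 had 2.20 (adjusted p = 0.0553) and Id1 1.20 (adjusted p = 0.149), neither past the test over all genes.

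With Cxcl12, 67 genes were higher and 48 lower in FLT3/ITD cells, 115 in all. Id1 was higher by 3.62 (SE 0.29, adjusted p = 0.00224), Pim1 by 2.76 (SE 0.38) and Alox5, the lipoxygenase of leukotriene synthesis, by 3.66 (SE 0.50). Serpina3g, a serine protease inhibitor, was at least 119-fold higher (adjusted p = 0.00224). Ctsg at -5.18 (SE 0.68), Clec7a at -4.62 (SE 0.39; 1 of 2 FLT3/ITD arrays above background) and Itga4 at -3.02 (SE 0.40) were lower. The correlation across genes between the sets was 0.359 without and 0.433 with Cxcl12. Without the term for the array set, limma called 0 genes in each of the 3 ITD comparisons, with 220, 369 and 716 genes at an unadjusted p under 0.05 without Cxcl12, with Cxcl12 and on average. The counts also depended on single arrays, and fell to 9, 17 and 153 when 1 array was left out. Each group had the same position on both slides, so neither a difference with ITD nor one with Cxcl12 can be told apart from one with position.

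With Cxcl12, averaged over both kinds of cell (4 arrays against 4), there was more mRNA of Acta1, Actc1, Dusp2 and Myc and less of Slc2a3 and Ddit4. Acta1, skeletal muscle actin, rose by 2.30 (SE 0.30, adjusted p = 0.0298; set 1 1.85, set 2 2.75) and Actc1, cardiac actin, by 1.72 (SE 0.15, adjusted p = 0.0127; set 1 1.59, set 2 1.86). Dusp2, a phosphatase that acts on MAP kinases, rose by 2.17 (SE 0.20, adjusted p = 0.0127; set 1 2.35, set 2 1.98), and the transcription factor gene Myc by 1.22 (SE 0.17, adjusted p = 0.0356; set 1 0.92, set 2 1.51). The glucose transporter Slc2a3 fell by 1.58 (SE 0.16, adjusted p = 0.0133; set 1 -1.74, set 2 -1.42). The mTORC1 inhibitor gene Ddit4 fell by 1.80 (SE 0.23, adjusted p = 0.0272; set 1 -1.45, set 2 -2.15). In this average Cxcl12 effect 53 genes passed the test, 21 higher and 32 lower, each in the same direction in both sets, which the test favours. The correlation across all genes between the sets was 0.406.

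**Figure D2:**
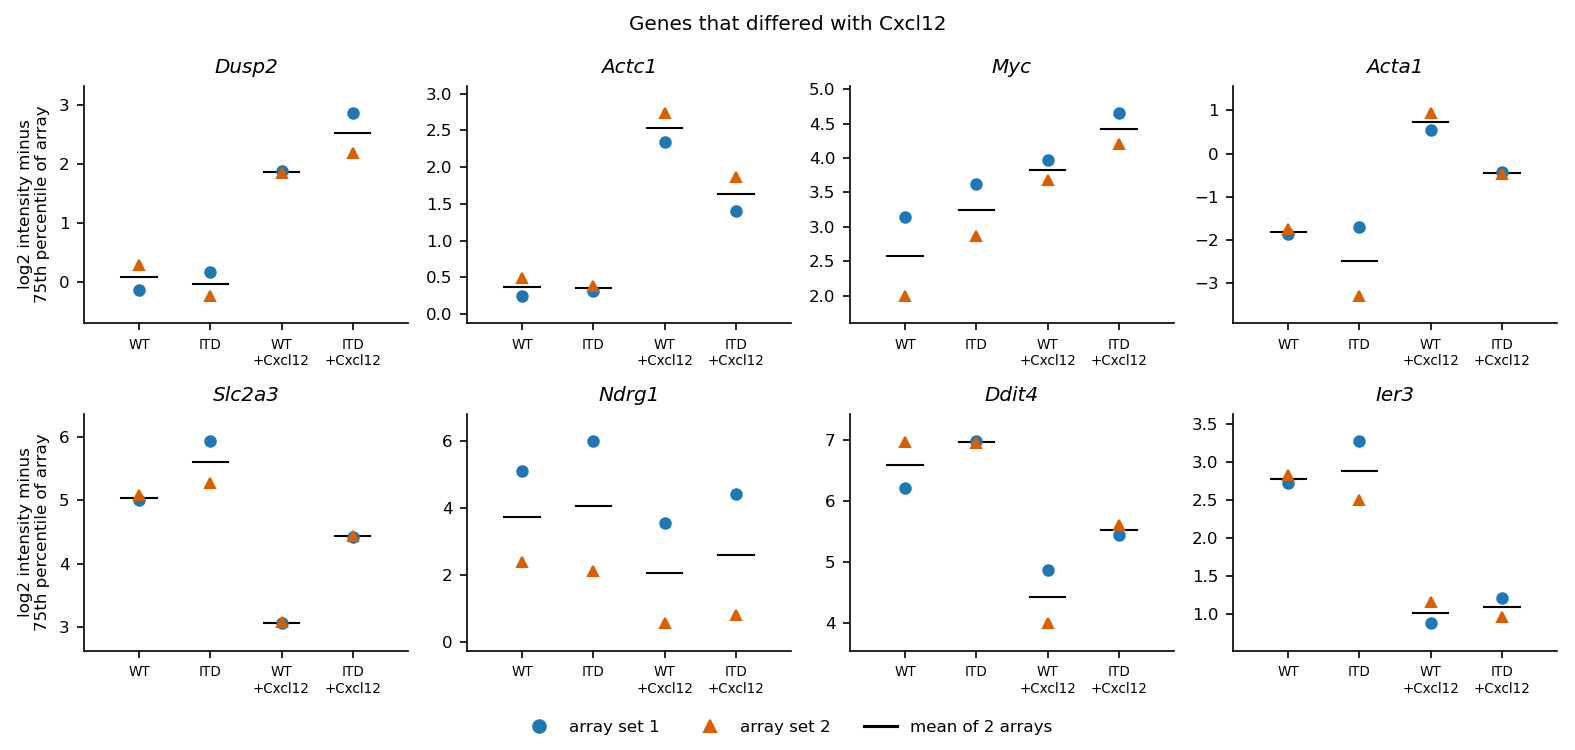
Log2 intensity minus the array's 75th percentile (vertical axes, a scale per panel) of 8 genes in wild type FLT3 (WT) and FLT3/ITD (ITD) cells without and with Cxcl12. Circles are set 1 arrays, triangles set 2 arrays and bars the mean of 2 arrays; in the average Cxcl12 effect Dusp2, Actc1, Myc and Acta1 rose by 2.17, 1.72, 1.22 and 2.30, while Slc2a3, Ndrg1, Ddit4 and Ier3 differed by -1.58, -1.57, -1.80 and -1.78.

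Other genes that rose were Cnn2, an actin-binding calponin, at 1.29 (SE 0.18), Tnfrsf12a at 1.23 (SE 0.17), the lipoprotein receptor Lrp8 at 1.22 (SE 0.17) and Mat2a, which makes S-adenosylmethionine, at 1.22 (SE 0.15). Gipr, the receptor of an incretin hormone, fell by 3.57 (SE 0.40; 3 of 4 Cxcl12 arrays above background) and Fxyd4, a regulator of the sodium pump, by 3.03 (SE 0.45; 1 of 4). Cdc42ep2, a CDC42 effector, fell by 2.10 (SE 0.26) and Ier3 by 1.78 (SE 0.20). The probes lie, in mm9, on chromosome 8 from 126416197 to 126416256 for Acta1, chromosome 2 from 113874011 to 113874934 for Actc1, chromosome 2 from 127163930 to 127163989 for Dusp2, and chromosome 6 from 122678075 to 122678134 for Slc2a3.

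Of 24 glycolysis and hypoxia genes 5 fell with Cxcl12, 0 rose and 19 did not pass (16 lower adjusted over the list alone). These were Slc2a3, Ndrg1 at -1.57 (SE 0.21), Ankrd37 at -1.47 (SE 0.21), P4ha1 at -1.21 (SE 0.19) and Slc2a1 at -0.96 (SE 0.15). Members that did not pass included Hk2 at -0.77 (adjusted p = 0.0886), Gpi1 at -0.47 (adjusted p = 0.0869) and Ldha at -0.18 (adjusted p = 0.62). The list's median was -0.51 (set 1 -0.63, set 2 -0.31, camera adjusted p = 4.9e-16, but adjusted p = 0.473 with an estimated correlation).

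Of 24 cholesterol synthesis and uptake genes 1 rose, 0 fell and 23 did not pass, while 21 were higher adjusted over the list alone. Mvk, mevalonate kinase, had 1.05 (SE 0.18, adjusted p = 0.0559) and Insig1 0.87 (SE 0.23, adjusted p = 0.134). The median was 0.62 (set 1 0.57, set 2 0.65, camera adjusted p = 4.9e-16, but adjusted p = 0.473 with an estimated correlation), and relative to all genes it was 0.34 with normexp against 0.61. Of 29 G1/S and DNA replication genes 0 passed and 5 were higher adjusted over the list alone, among them the cyclin genes Ccne1 at 1.19 (adjusted p = 0.0607) and Ccne2 at 0.85 (adjusted p = 0.0965). Their median was 0.24 (set 1 0.35, set 2 0.18, camera adjusted p = 1.26e-05, but adjusted p = 0.629 with an estimated correlation). Of 27 MYC targets and ribosome biogenesis genes Ppan rose, by 1.09 (SE 0.17), and 26 did not pass (1 adjusted over the list alone; median 0.20, set 1 0.50, set 2 -0.03, camera adjusted p = 0.00137, but adjusted p = 0.688 with an estimated correlation). With normexp, the medians of these last 2 lists relative to the median of all genes were -0.03 and -0.04, and both calls were lost.

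Of 18 p53 targets 0 passed and 8 were lower adjusted over the list alone. The sestrin gene Sesn2 had -1.34 (adjusted p = 0.0605), Bbc3, which encodes the death-promoting protein PUMA, -0.85 (adjusted p = 0.073) and the cyclin-dependent kinase inhibitor Cdkn1a -0.82 (adjusted p = 0.0673). The median was -0.50 (set 1 -0.34, set 2 -0.72, camera adjusted p = 7.09e-07, but adjusted p = 0.587 with an estimated correlation). Of 20 genes of the ATF4 and amino acid response Ddit4 fell and 19 did not pass (6 lower adjusted over the list alone), with Trib3 at -1.66 (adjusted p = 0.0841) and Phgdh at 0.20 (adjusted p = 0.587). This list had a median of -0.28 (set 1 -0.21, set 2 -0.36, camera adjusted p = 1.97e-05, but adjusted p = 0.587 with an estimated correlation), and relative to all genes -0.61 with normexp. Of 14 FOXO targets 0 passed, and 5 were lower and 1 higher adjusted over the list alone, with Ccng2 at -1.23 (adjusted p = 0.0577) and Tsc22d3 at -1.14 (adjusted p = 0.0546; list median -0.36, set 1 -0.56, set 2 -0.27, camera adjusted p = 0.00613, but adjusted p = 0.629 with an estimated correlation).

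Of 16 immediate-early genes only Dusp2 passed (4 higher and 4 lower adjusted over the list alone). Egr2 had 2.70 (SE 0.65, adjusted p = 0.113) and Fos 1.87 (SE 0.43, adjusted p = 0.0988), against -1.16 for Jun (SE 0.25, adjusted p = 0.0886) and -0.94 for Jund (SE 0.16, adjusted p = 0.0512). The list's median was 0.40 (set 1 -0.12, set 2 0.38, camera adjusted p = 0.43). Of 15 NF-kB targets Tnfaip3, which encodes the inhibitor A20, fell by 1.20 (SE 0.16), and 14 did not pass (list median -0.28, camera adjusted p = 0.0507). Of 6 neutrophil and granule markers 0 passed and 2 were lower adjusted over the list alone, S100a9 at -1.90 (1 of 4 Cxcl12 arrays above background) and Prtn3 at -1.23 (median -1.17, set 1 -0.94, set 2 -1.13, camera adjusted p = 0.0125, but adjusted p = 0.5 with an estimated correlation). With normexp the median of the list relative to all genes was -0.36 (camera adjusted p = 0.000515), against -1.175 in the main analysis. Of 14 mast cell and basophil markers 0 passed and 2 were lower adjusted over the list alone, Mcpt8 at -1.11 and Cd200r3 at -0.71 (median -0.18, set 1 -0.13, set 2 -0.26, camera adjusted p = 0.045, but adjusted p = 0.629 with an estimated correlation). The 25 CXCR4 signalling and migration genes had a median of -0.09 and 0 passed (camera adjusted p = 0.408). With normexp the median of this list relative to all genes was -0.35 and the list passed (camera adjusted p = 0.0158). Immediate-early genes (camera adjusted p = 0.00124) and T and NK cell markers (adjusted p = 0.00383) also passed with normexp, and NF-kB targets with quantile normalization (adjusted p = 0.0484) and the authors' tables (adjusted p = 0.0486).

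**Figure D3:**
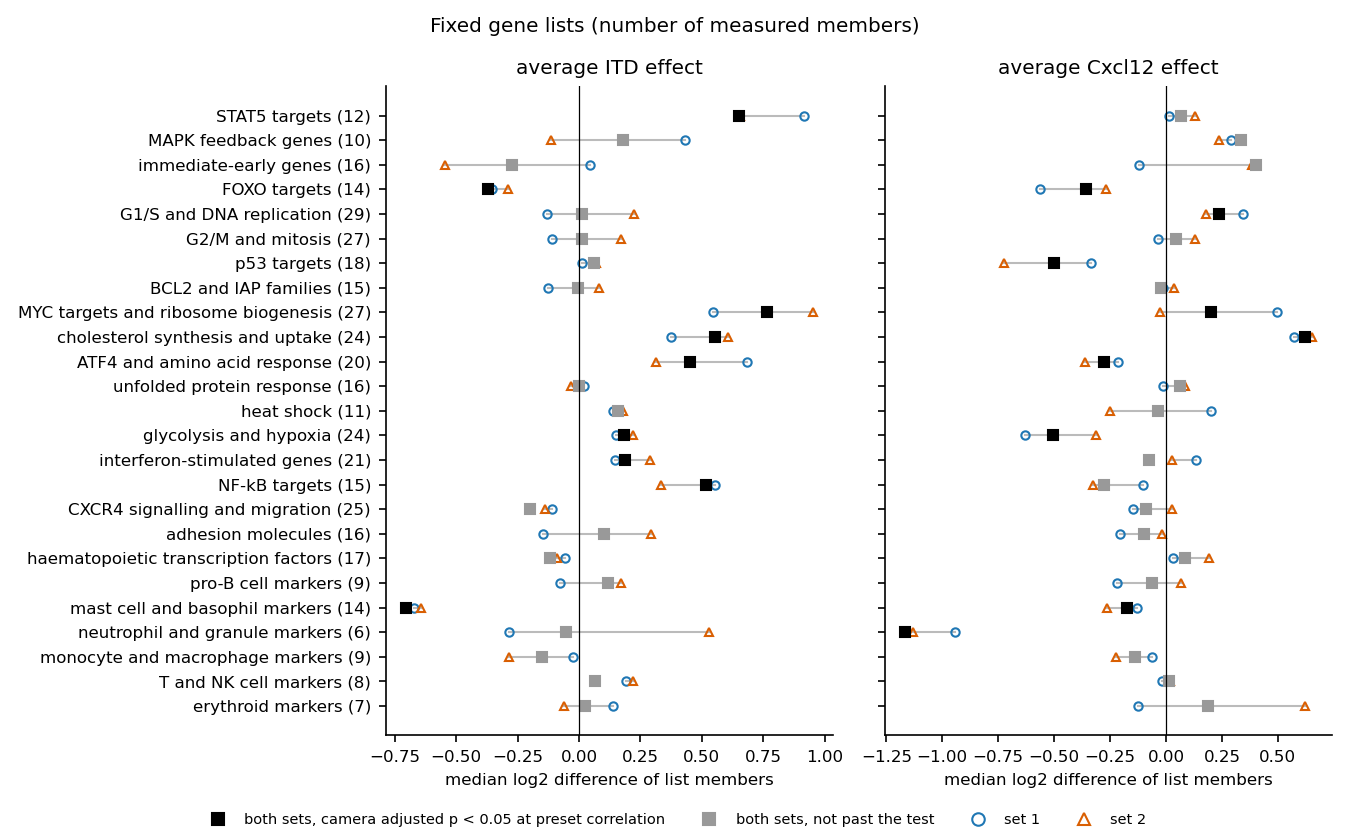
Median log2 difference of the members of each of 25 fixed gene lists (horizontal axis) in the average ITD effect (left) and the average Cxcl12 effect (right), with the number of measured members in brackets. Squares are both sets together, black where the camera test passed with the preset correlation and grey where it did not, circles are set 1 and triangles set 2; MYC targets lie at 0.77 on the left, and glycolysis and hypoxia at -0.51 and cholesterol synthesis at 0.62 on the right.

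In wild type FLT3 cells alone, 9 genes passed, 1 higher and 8 lower with Cxcl12, each with an adjusted p of 0.043. Actc1 rose by 2.16 (SE 0.22). Gipr fell by 4.57 (SE 0.57; 1 of 2 Cxcl12 arrays above background), Slc2a3 by 1.98 (SE 0.23) and Fam162a, a hypoxia-induced mitochondrial protein, by 1.51 (SE 0.19). The near-identical genes Selenbp1 and Selenbp2 fell by 1.81 (SE 0.23) and 1.77 (SE 0.21), the corepressor gene Rcor2 by 1.56 (SE 0.20) and 5830408C22Rik by 2.81 (SE 0.35). The count was 0 with quantile normalization, with the mean of probes, without the variance trend, without a filter and without any one of 4 of the 8 arrays. Genes at least 2-fold different in both sets that did not pass included Egr2 at 3.11 (adjusted p = 0.454), Acta1 at 2.55 (adjusted p = 0.138), Fos at 1.96 (adjusted p = 0.489), Dusp2 at 1.79 (adjusted p = 0.126) and the smooth muscle actin gene Acta2 at 1.48 (adjusted p = 0.136).

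In FLT3/ITD cells alone, limma called 0 genes with Cxcl12, and 1431 had an unadjusted p under 0.05, where chance would give 687. The smallest adjusted p was 0.129, for Dusp2 at 2.54 (SE 0.28; set 1 2.68, set 2 2.41). Acta1 had 2.05 (adjusted p = 0.292), Myc 1.18 (adjusted p = 0.292) and Gipr -2.57 (adjusted p = 0.292). Prg2 had -3.10 (SE 1.11, adjusted p = 0.402) and Epx -2.94 (SE 1.18, adjusted p = 0.455), neither past the test. The correlation across genes between the sets was 0.32 in wild type FLT3 and 0.307 in FLT3/ITD cells. Without the term for the array set, limma called 0 genes in wild type FLT3 cells (120 at an unadjusted p under 0.05), 0 in FLT3/ITD cells (123) and 0 in the average Cxcl12 effect (309). The average count of 53 fell to 0 without the set 1 array of FLT3/ITD with Cxcl12, and also without the set 2 array of wild type FLT3 with Cxcl12. It rose to 208 without the set 2 array of FLT3/ITD with Cxcl12.

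Whether the difference with Cxcl12 was larger or smaller in FLT3/ITD cells was tested as the interaction of ITD and Cxcl12. No gene passed by limma: 0 of 13740, with 235 at an unadjusted p under 0.05 where chance would give 687 and a smallest adjusted p of 1. The correlation across genes between the sets was 0.068. Id1 had -1.13 (SE 0.29) with Cxcl12 in wild type FLT3 cells and 1.30 (SE 0.29) in FLT3/ITD cells, an interaction of 2.42 (SE 0.41; set 1 2.04, set 2 2.81) that passed adjusted over the list alone in 2 lists, STAT5 targets and haematopoietic transcription factors. With normexp the difference in wild type FLT3 cells was -0.41. Of 24 glycolysis and hypoxia genes 22 had a positive interaction, so that the negative difference was smaller in size in FLT3/ITD cells for most of them, and 0 passed. Slc2a1 had -1.45 (SE 0.21) in wild type FLT3 and -0.47 (SE 0.21) in FLT3/ITD cells, Hk2 -1.34 (SE 0.24) and -0.21 (SE 0.24), and Ndrg1 -1.69 (SE 0.29) and -1.46 (SE 0.29). The list's median interaction was 0.40 (set 1 0.29, set 2 0.44, camera adjusted p = 9.39e-07, but adjusted p = 0.877 with an estimated correlation). Relative to all genes it was 0.33, against 0.22 with quantile normalization and 0.80 with normexp.

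**Figure D4:**
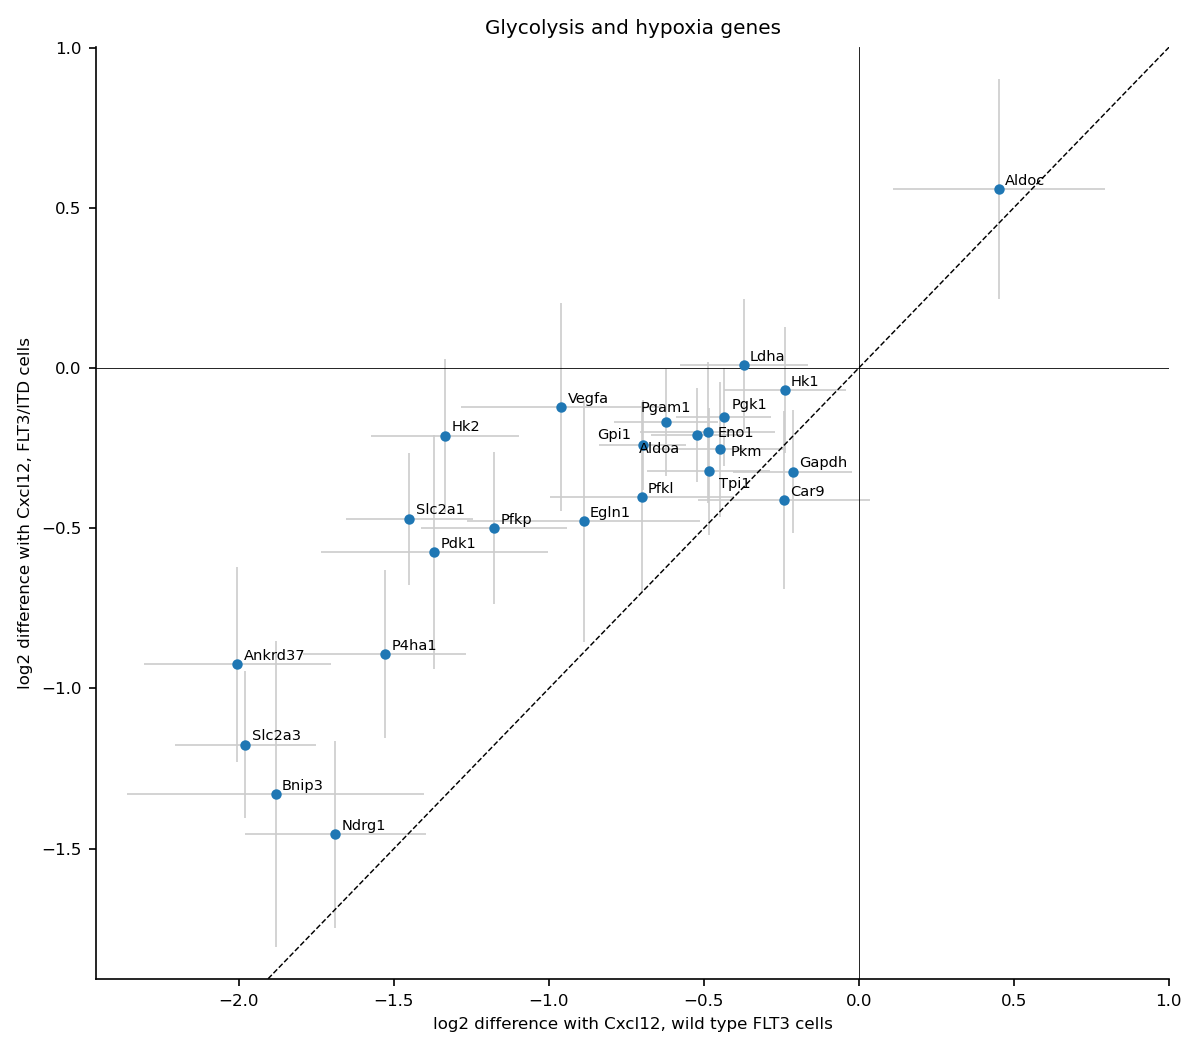
Log2 difference with Cxcl12 in wild type FLT3 cells (horizontal axis) and FLT3/ITD cells (vertical axis) of 24 glycolysis and hypoxia genes, with error bars of 1 SE and a dashed line of equal difference. Of the 24 genes 22 lie above the line, among them Slc2a1 at -1.45 and -0.47 and Hk2 at -1.34 and -0.21.

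Of the 25 lists 2 others passed in the interaction. The 12 STAT5 targets had a median of 0.38 (set 1 0.50, set 2 0.14, camera adjusted p = 0.0358, but adjusted p = 0.877 with an estimated correlation), with Cish at 1.61 (SE 0.69) beside Id1. The 11 heat shock genes had a median of 0.41 (set 1 0.14, set 2 0.39, camera adjusted p = 0.0481, but adjusted p = 0.877 with an estimated correlation), with Dnajb1 at 1.09 (SE 0.36) and Hsph1 at 1.33 (SE 0.79). The call of STAT5 targets was lost with normexp (adjusted p = 0.0505), while the list's median relative to all genes was 0.39 there and 0.32 in the main fit. That of heat shock genes was lost with quantile normalization, and the median relative to all genes was 0.66 with normexp against 0.35. With 1 array left out the call of STAT5 targets was lost in 4 of 8 cases, that of heat shock genes in 5 and that of glycolysis and hypoxia in 1. Without the set 1 array of FLT3/ITD with Cxcl12, or the set 2 array of wild type FLT3, 3 lists passed, 1 higher and 2 lower. With normexp G1/S and DNA replication (camera adjusted p = 0.0103), MYC targets (adjusted p = 0.00213) and the unfolded protein response (adjusted p = 0.00247) passed as well.

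Genes called in both the average ITD and the average Cxcl12 effect numbered 5, where 3.27 would be shared by chance (Fisher's exact test, two-sided p = 0.38). This depended on the processing, with 16 shared against 2.27 expected with normexp (p = 7e-10) and 31 against 13.6 with the authors' tables (p = 1.08e-05). Tmem238 rose in both and Fcgr2b, an inhibitory Fc receptor, fell in both, by 2.07 with ITD and 1.48 with Cxcl12. Slc2a3 and Fam162a rose with ITD and fell with Cxcl12, the latter by 0.85 on the log2 scale in each case. Adcy7, an adenylate cyclase, fell by 0.67 with ITD and rose by 1.08 with Cxcl12.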

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

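The tests of mast cells in the wild type cultures, of position on the slide and of Id1 against chance among all genes were chosen after the result was seen. With 2 arrays per group no array was tested as an outlier within its group. Without the set 2 array of FLT3/ITD with Cxcl12 the counts rose from 53 to 208 for the average Cxcl12 effect and from 0 to 58 for Cxcl12 in FLT3/ITD cells.

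The difference with Cxcl12 was not the same in FLT3/ITD and wild type FLT3 cells for 3 lists by camera with the preset correlation: STAT5 targets (adjusted p = 0.0358), heat shock (adjusted p = 0.0481) and glycolysis and hypoxia (adjusted p = 9.39e-07). With an estimated correlation all 3 had an adjusted p of 0.877. Id1 differed between the cells adjusted over the list alone, in STAT5 targets (adjusted p = 0.0028) and in haematopoietic transcription factors (adjusted p = 0.00396). The Flt3 probe, left out by the filter, was well above background on 4 arrays, all of set 2.

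The mast cell and basophil genes that fell in FLT3/ITD cells (Mcpt8, Mcpt4, Cma1, Cma2 and Cd200r3) kept negative differences under each scaling of the arrays. The difference nearest to 0 was -1.69, for Cd200r3 with normexp, so scaling alone did not give it. Mast cells or basophils in the wild type cultures would leave markers that Ba/F3 cells do not express lower in FLT3/ITD cells. Which markers these are was not tested. The 9 members outside the Mcpt, Cma and Prss34 genes, Cpa3 and Cd200r3 among them, had a median of -0.48 (set 1 -0.23, set 2 -0.44). The SE of these medians, 0.40 in set 1 and 0.36 in set 2, is from the spread between the 9 genes. It takes them as independent and does not measure the spread between arrays. The median therefore cannot tell such cells from a change within Ba/F3 cells.

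Lower glycolysis and hypoxia genes with Cxcl12 were present under each scaling, with a list median relative to all genes of -0.504 at its nearest to 0, with quantile normalization. The authors' tables differ from the main values by a near-constant factor per array. A median relative to all genes removes that factor, so these tables could not change the result. Of 1000 random lists of the same brightness 0 had a median as low, a test that ignores correlation between the genes (0.258 as estimated for this list). On 0 slides did the groups lie in another order, so position on the slide cannot be told apart from Cxcl12. For the smaller difference in FLT3/ITD cells 0 of 1000 random lists were as high, with the same limit. Its size relative to all genes was 0.334 in the main analysis and 0.224 with quantile normalization. The SE of the latter, 0.095, is from the spread between the list's genes taken as independent, not between arrays. The part that scaling plays therefore cannot be told. With normexp, which also changes the background correction, the size was 0.80. No biological explanation was tested.

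The opposite differences of Id1 with Cxcl12 kept an interaction of at least 1.61 (normexp, SE 0.59) under each scaling, and both Id1 probes had the same directions. The difference in wild type FLT3 cells was -0.41 with normexp against -1.13 in the main analysis, so the size of the negative part depends on the processing. By chance 3.2 genes would have an interaction p as small (0.000233), and 2 were observed. The expected number takes p-values as evenly spread, but 235 genes had an interaction p under 0.05 where chance would give 687. The comparison is therefore no close measure of chance. Chance among all genes tested is not excluded for Id1, and no biological explanation was tested.

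Of 35 splits of the 8 arrays into 4 and 4, 2 called as many genes as the average ITD effect (847), the real one included, the other being the split by slide (7188 genes). Among the 18 splits even over the slides only the real one did, and the next highest called 15. The fits of the other splits do not model ITD, so its differences add to their residual spread and can lower their counts. The gap to 15 is therefore no measure of chance. For the average Cxcl12 effect (53 genes) 3 did, the real one, the split by slide (8565) and the split by ITD (650), the latter also even over the slides. The split by slide was fitted with 4 parameters and the split by ITD with 3, against 5 for the real ones, and both follow a known factor, so these counts are not a fair measure of chance, which the splits do not exclude. The many genes called by slide show that the slides differ. Whether this comes from the samples or from the arrays and their processing, such as the Feature Extraction version, cannot be told.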

How the results depend on the processing

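None of these alternatives was chosen after the result was seen, but Fisher's tests of shared genes under them were, and the cause of a change was not tested. Of 163 named gene results past the test, 157 stayed with the authors' tables, 134 with the mean of a gene's probes, 120 with quantile normalization, 100 without the variance trend, 90 with normexp, 48 without a filter and 101 of 101 on bright probes. Over the 8 fits with an array left out 798 of 1304 such results stayed. Of 54 list calls 39 stayed with normexp, 51 with quantile normalization, 38 without a filter and 52 with the authors' tables. Those tables differ from the main values by a near-constant factor per array. Camera compares a list with all other genes, so this factor largely drops out and the 52 are a weak check.

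Without the replicate block the counts were 0 genes in all 7 comparisons and 0 shared genes, so every gene call rests on the array set in the model, while 50 of 54 list calls stayed. With an estimated correlation 0 lists passed in the average ITD effect, 0 in the average Cxcl12 effect and 0 in the interaction. That test also has fewer degrees of freedom, so the loss cannot be laid to correlation between genes alone.

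With normexp the counts were 196 for ITD with Cxcl12, 29 for Cxcl12 in FLT3/ITD cells, 6 for the interaction, 362 for average ITD, 86 for average Cxcl12, 5 lists for the interaction and 16 shared genes, and the correlation between sets was 0.266, 0.04, 0.188, 0.302 and 0.022 for ITD with Cxcl12, Cxcl12 in wild type cells, interaction, average ITD and average Cxcl12. With quantile normalization they were 32 for ITD without Cxcl12, 0 for Cxcl12 in wild type cells, 31 for average Cxcl12 and 1 shared gene. Without a filter (27091 genes) they were 1 and 21 for ITD without and with Cxcl12, 0 for Cxcl12 in wild type cells, 179 and 0 for the averages, 1 list for the interaction and 0 shared genes, with correlations between sets of 0.123, 0.225, 0.102, 0.137, -0.023 (interaction, of the opposite sign), 0.272 and 0.22. On probes above background on all 8 arrays (11939 genes) they were 42 for ITD without Cxcl12, 93 for average Cxcl12 and 12 shared. With the mean of probes they were 0 for Cxcl12 in wild type cells, 6 lists for the interaction and 1 shared. Without the trend they were 0 and 1 for Cxcl12 in wild type and FLT3/ITD cells, 449 and 6 for the averages, 1 list for the interaction and 0 shared. With the authors' tables they were 170 and 195 for ITD without and with Cxcl12, 3 for Cxcl12 in FLT3/ITD cells, 151 for average Cxcl12 and 31 shared. There 75.9% against 54.3% of called genes were higher for ITD without Cxcl12, 75.7% against 58.1% for average ITD and 30% against 11.1% for Cxcl12 in wild type cells. The median of all genes moved to 0.188, 0.112, -0.156 and 0.116 for ITD without Cxcl12, Cxcl12 in wild type cells, interaction and average ITD with the authors' tables, and to 0.153, -0.131 and 0.181 for ITD with Cxcl12, Cxcl12 in wild type cells and interaction with normexp.

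For lists the direction is that of the camera test, and a reversal was counted where either fit passed. Of 7 list reversals with normexp 2 were of lists that had passed in the main fit, G1/S and MYC targets in Cxcl12 in wild type cells. The others had no called direction there, such as G1/S in ITD with Cxcl12 (median 0.075, camera adjusted p = 0.972). The direction reversed with normexp for G1/S (adjusted p = 0.0164) and G2/M (0.0234) in ITD with Cxcl12. In Cxcl12 in wild type cells it did so for G1/S (0.378), G2/M (0.0394), MYC targets (0.162) and T and NK cell markers (0.00395). The direction also reversed for G1/S in the interaction (0.0103), Lyz1 in ITD with Cxcl12 (-0.68), Lta (-0.47) and Usp18 (-0.16). It reversed without the set 2 FLT3/ITD array for immediate-early genes (0.00453) and G1/S (0.000543) in ITD without Cxcl12 and G1/S in the interaction (0.00517), and without the set 1 FLT3/ITD array for MYC targets in Cxcl12 in FLT3/ITD cells (0.555) and the interaction (0.000677). With an array left out the adjusted p ranged from 0.00453 to 0.83 for the result immediate-early genes, ITD effect without Cxcl12, and from 0.000543 to 0.975 for G1/S and DNA replication, ITD effect without Cxcl12. It ranged from 2.55e-08 to 0.555 for MYC targets and ribosome biogenesis, Cxcl12 effect in FLT3/ITD cells, from 0.000369 to 0.916 for G1/S and DNA replication, interaction of ITD and Cxcl12, and from 2.78e-05 to 0.74 for MYC targets and ribosome biogenesis, interaction of ITD and Cxcl12.

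With an array left out counts ranged from 9 to 83 for ITD without Cxcl12, 17 to 215 with it, 0 to 13 and 0 to 58 for Cxcl12 in wild type and FLT3/ITD cells, 0 to 22 for the interaction, 153 to 928 and 0 to 208 for the averages, 7 to 10, 8 to 11 and 1 to 9 for lists of average ITD, average Cxcl12 and interaction, and 0 to 56 shared. Counts changed more than 1.5-fold as follows, where W, I, WC and IC stand for wild type, FLT3/ITD and each with Cxcl12, and 1 or 2 for the set of the array left out. ITD without Cxcl12 had 29 without W1, 9 without I1, 21 without W2 and 18 without I2, and ITD with Cxcl12 had 24 without WC1, 39 without IC1, 17 without WC2 and 215 without IC2. Cxcl12 in wild type cells had 2 without W1, 3 without WC1, and 0 without I1, W2, I2 or WC2. Cxcl12 in FLT3/ITD cells had 1 without W1, I1 or W2, 10 without I2 and 58 without IC2. The interaction had 1 without W1 or I1, 7 without I2 and 22 without IC2. Average ITD had 199 without WC1, 449 without IC1, 309 without W2, 165 without I2 and 153 without WC2. Average Cxcl12 had 35 without W1, 6 without I1, 23 without WC1, 3 without W2, 208 without IC2, and 0 without IC1 or WC2. Interaction lists numbered 6 without W1, 5 without I1, 9 without WC1, 7 without I2 and 1 without IC2. Shared genes numbered 12 without W1, 9 without I2, 56 without IC2 (11.6 expected), and 0 without IC1, W2 or WC2. With an array left out the 2 averages share error, which can raise this count.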

Other observations

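The SRF list below and its tests were chosen after the actin genes were seen, and the other values were not tested further.

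Some further genes differed with Cxcl12 on average. Acta2 rose by 1.07 (SE 0.17, adjusted p = 0.0465), and Tnnc1, a troponin C, fell by 1.58 (SE 0.24, adjusted p = 0.0396, 2 of 4 Cxcl12 arrays above background). Myl10, a myosin light chain, fell by 2.56 (SE 0.37, adjusted p = 0.0378), with 1 of 4 Cxcl12 arrays and 3 of 4 others above background. Fosl1 had 1.66 (SE 0.41, adjusted p = 0.119) and the cyclin gene Ccnf 1.06 (SE 0.20, adjusted p = 0.066), against -0.97 for the cyclin-dependent kinase inhibitor Cdkn1b (SE 0.27, adjusted p = 0.147).

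A hypothesis was that the higher actin genes belong to a shared response of cytoskeletal genes that serum response factor (SRF) regulates. Of 27 such genes without the actin genes that led to the idea 20 were measured, 17 of them higher with Cxcl12 (median 0.37, set 1 0.44, set 2 0.32). Of 1000 random lists of the same brightness 0 had a median as high, a test that ignores correlation between the genes. By camera the list had an unadjusted p of 1.52e-05 with the preset and 0.0297 with the estimated correlation. None passed the limma test over all genes, and 3 did adjusted over the list alone, Actg1 at 0.90 (SE 0.15), Tpm4 at 0.83 (SE 0.16) and Flna at 0.54 (SE 0.12), while Actb had -0.04 (SE 0.17). Relative to all genes the median was 0.35 with quantile normalization and 0.066 with normexp, so its size depends on the processing. It was 0.361 with the authors' tables, whose scaling cannot change a median relative to all genes. SRF activity was not measured here, and the hypothesis remains open.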
